A study of Mus musculus with 2 samples.

How the data were processed

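Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse lung at embryonic day 14.5. Per the labels, the 2 samples are biological replicates, made from the pooled lungs of 24 embryos for replicate 1 and 34 embryos for replicate 2, with both sexes in each pool. They form 1 group with no treatment and no second tissue or age. The comparisons are therefore between the replicates, between kinds of genomic location, between gene lists fixed beforehand and other genes, and between peak sequences and matched sequences.

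The authors deposited lists of peaks, which are intervals with more signal than background, and not reads or counts. Per the deposited readme files, the intervals are in narrowPeak format on mouse assembly mm10. Each sample has a list of its own, called from its alignments and 2 further inputs that are not described there, and a pooled list was called from both samples' alignments with the same inputs. A replicated list was derived from the pooled list and both samples' lists, per the same readme files. The peak caller, its settings and the aligner are not given in the sources used here. Each peak carries the authors' signal value, whose scale is also not given, and the −log10 p and −log10 q that the authors' caller assigned. Signal values were used only to describe, rank or filter peaks within 1 list, because values and ranks from lists of different lengths show no change between samples. The lowest −log10 p in the deposited lists was 2.03, so peaks of weak evidence are included. The lists hold no read counts, so sequencing depth per sample is unknown, and no interval or detection limit that needs depth was computed.

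The replicated list was the main list and each sample's own list gave the spread between replicates. Of the 59767 replicated peaks, 14970 did not overlap, by even 1 bp, a peak in each replicate's own list. A replicated peak is therefore not always one seen in both samples' lists. Peaks on chromosomes 1 to 19, X and Y were used. The reference was assembly GRCm38 patch 6, the same build as mm10, with GENCODE release M21. It has 21938 protein-coding genes on these chromosomes, and 21911 with 1 kept per symbol, which were used. No peak ran past the end of a chromosome. Peaks of the 2 replicates were counted as shared at an overlap of at least 1 bp. Overlap by chance and chance location came from 100 random placements of the peaks within their chromosomes. A peak was placed by its summit as promoter (within 1 kb of any annotated transcription start site, TSS, coding or not), then exon, intron or intergenic. A protein-coding gene was counted as having a marked promoter when a peak lay within 1 kb of any of its annotated TSSs, and unmarked means without one in the replicated list. Distal peaks lay wholly over 2.5 kb from every TSS, and a gene's distal count covered 100 kb around its TSSs. Domains were peaks merged over gaps of up to 1 kb that overlapped a protein-coding TSS, and the 500 genes with the widest, which held 420 distinct domains, were compared with other genes that had one. Distal peaks within 10 kb of each other were stitched into clusters, which were ranked by the summed product of signal value and width. This ranks peak lists and is not a call of super-enhancers, since no input-subtracted reads were available here. Windows of 201 bp around distal summits were searched on both strands for 22 consensus sequences and compared with windows outside peaks and over 2.5 kb from TSSs, matched on GC content.

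Gene lists were tested with Fisher's exact test, two-sided, for promoters, domains and clusters. Distal counts were tested with a two-sided permutation test against 10000 random gene lists matched on the number of genes within 100 kb. Motifs were tested with Fisher's exact test. The p-values of these tests were adjusted by the Benjamini-Hochberg method over the 32 lists or 22 motifs, or over the lists with a member that could be tested, at a threshold of 0.05. Permutation p-values on the 3 further lists described below, and on the fixed lists compared with them, are not adjusted. The smallest two-sided p that the permutations can give is 0.00020. Genes and peaks are not replicates: these tests compare list members with other genes in this one tissue and do not measure differences between animals, and neighbouring genes such as those of a Hox cluster are not independent. Intervals on shares are 95% Wilson intervals and cover counting error only.

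The 32 gene lists, the motifs, the tests and the rule for named genes were fixed before the data were examined. Of 623 symbols, 622 matched the annotation, Ctsv being the exception. By the rule, text names up to 4 members with the highest promoter signal value and up to 2 unmarked members, alphabetically first, of each list that passes. Every marked member, or the 6 highest, is named for lists of tissues other than lung, together with the 10 widest domains and the 10 highest clusters. Nkx2-1, Foxf1, Tbx4, Shh, Sftpc, Hoxa5 and Hoxb5 are named whatever their values. Other genes named were chosen after their values were seen. Later, 3 further lists of 25 cardiac, 24 erythroid and 23 hepatocyte genes, which share no gene with the fixed lists, were written before their values were seen and used to test explanations.

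The alternatives fixed beforehand were the pooled list, each replicate's own list alone, the stronger part of the replicated list, peaks with −log10 q of at least 5, and other overlap rules. They also covered promoter windows of 500 bp and 2.5 kb, a single TSS per gene, random lists matched on promoter CpG content in 10 bins, and other distal, domain, cluster and motif settings. Alternatives chosen after seeing the data were replicate 2 shortened to its strongest peaks, as many as replicate 1 has, distal peaks around the gene's 5′ end alone, a background without olfactory and vomeronasal receptor genes, and motif windows without repeat-masked bases.

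Each test was run on simulated data. With 10 of 32 lists planted as changed in the promoter test over 21911 genes, 10 were recovered and 0 of the 22 other lists were called. The distal test over the same genes recovered 5 of 5 planted lists and called 0 of 27 others, and the cluster test over 8387 genes recovered 5 of 5 and called 0 of 26. The domain test over 11730 genes recovered 5 of 5 and called 1 of 27 others, Hox paralog groups 1 to 5, whose neighbouring members share merged domains. The motif test over 35000 windows recovered 5 of 5 planted motifs and called 0 of 17 others. In these simulations both sets of windows were uniform random bases, and unplanted genes had promoter peaks at a single rate, whatever their CpG content. The simulations therefore do not show how often repeats, base composition or CpG content lead to a call. Changes were planted at set sizes, and background distal peaks lay at uniform random positions. Recovery of smaller changes, and calls where peaks cluster, were thus not measured. Overlap counts made independently and with bedtools differed at 0 of 5000 intervals. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, bedtools 2.31.1 and samtools 1.23.1.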

Results

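H3K27ac ChIP-seq of embryonic day 14.5 mouse lung gave 71225 peaks in replicate 1 (a pool of 24 embryos) and 122253 in replicate 2 (34 embryos) on the main chromosomes. The lung of this age consists of branching epithelial tubes in mesenchyme with a growing vascular bed. Peaks covered 35.4 Mb (1.30% of the genome) in replicate 1 and 62.6 Mb (2.3%) in replicate 2, and their median widths were 313 and 304 bp. The authors' replicated list held 59767 peaks over 46.9 Mb with a median width of 532 bp, and their pooled list held 89300 peaks over 54.1 Mb. Replicate 2 had 1.72 times as many peaks as replicate 1. The sequencing depth behind the lists is unknown.

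The strongest acetylated regions were shared by both lung pools almost without exception, and the replicates parted at weak peaks. In replicate 1, 55899 of 71225 peaks overlapped a peak of replicate 2 (78.5%, 95% Wilson interval 78.2 to 78.8%), against 4.55% for random placement. In replicate 2, 48479 of 122253 peaks overlapped replicate 1 (39.7%, 39.4 to 39.9%), against 2.67%. Among the strongest 10% of peaks the shared portion was 99.96% in replicate 1 and 99.7% in replicate 2, and among the weakest 10% 60.7% and 13.4%. Across 44797 replicated peaks the authors' signal value in one sample's list ranked with that in the other at a Spearman rho of 0.714, described across peaks, which are not replicates. Rho was 0.840 at 15904 promoter peaks and 0.575 at 28893 other peaks. With each list held to its 71225 strongest peaks, the overlap was 69.5% of replicate 1 and 57% of replicate 2.

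**Figure D1:**
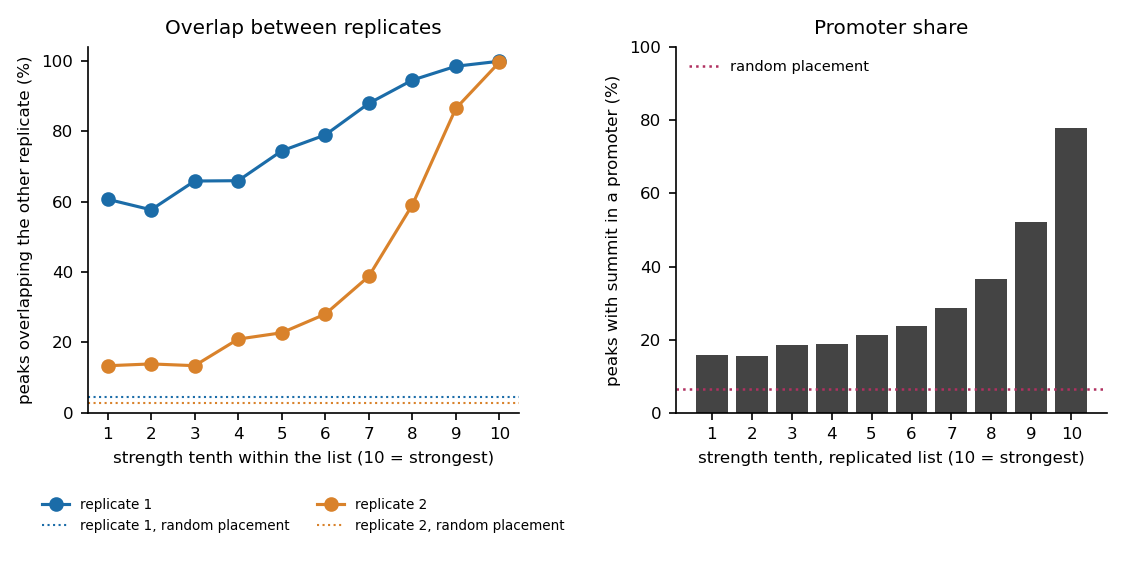
Left, percentage of each replicate's peaks that overlap the other replicate's list by at least 1 bp, in 10 equal bins of the authors' signal value within the list, with dotted lines for random placement. Right, percentage of replicated peaks with their summit within 1 kb of a TSS, in 10 equal bins of signal value, 15.8% in the weakest and 77.9% in the strongest.

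Acetylation lay at promoters far more often than chance and elsewhere mostly within introns. Promoters held 18481 replicated peaks (30.9%), 4.83 times the 6.40% of random placement. The promoter portion was 26.2% ± 5.58 (SD, n = 2) over the replicates' own lists, 30.1% in replicate 1 and 22.2% in replicate 2. Introns held 40.6% of replicated peaks, against 40.4% by chance, and exons 3.68%, against 3.41%. Intergenic sequence held 24.8%, 0.498 times its chance value of 49.8%. The promoter portion was 15.8% in the weakest 10% of peaks and 77.9% in the strongest 10%. Of 21911 protein-coding genes, 11732 had a marked promoter (53.5%), and the replicates gave 56.0% ± 4.23 (SD, n = 2). The marked portion was 3.47% in the 10% of genes with the lowest ratio of observed to expected promoter CpGs and 92.5% in the 10% with the highest.

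Genes of the lung epithelial progenitor and of the lung mesenchyme were marked nearly throughout. All 30 promoters of the epithelial progenitor list were marked in the replicated list and in both replicates, against 53.5% of other genes (Fisher's exact test, adjusted p = 3.43e-07). They include Nkx2-1, the transcription factor that specifies lung from foregut endoderm, the transcriptional regulators Id2 and Irx3, the secreted signal Shh, and Fgfr2, the receptor for mesenchymal Fgf10. Signal values within the replicated list were 23.0 for Nkx2-1, 27.5 for Id2, 24.5 for Irx3 and 21.9 for Shh. For Fgfr2 the highest value, 32.5, lay at an annotated TSS that is also the promoter of Ctbp2, and the highest at its other TSSs was 14.2. In the mesenchyme list 29 of 30 promoters were marked (96.7%; 95% ± 2.36, SD, n = 2 replicates; Fisher's exact test, adjusted p = 3.08e-06), with Barx1 the exception. The highest values were at Ptch1, the Hedgehog receptor (42.6), Zeb2 (31.2), Gli3, a Hedgehog effector (29.5), and Foxf1, a regulator of lung mesenchyme (28.9). Both lists passed against random lists matched on promoter CpG content, whose mean shares were 74.8% and 68.5% (permutation test, adjusted p = 0.000800 for each, from the smallest p the permutations can give).

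Vascular and smooth muscle genes were marked as well. In the endothelium list 25 of 28 promoters were marked (89.3%, Fisher's exact test, adjusted p = 0.00020), 89.3% ± 10.1 (SD, n = 2) in the replicates, against 52.3% in CpG-matched lists. Ets1 (signal value 15.3) and Fli1 (13.6), transcription factors of endothelial cells, Egfl7 (13.8) and Esam, an endothelial adhesion molecule (11.2), ranked highest, Flt4 was unmarked and Sox7 was marked in replicate 2 alone. The smooth muscle and pericyte list had 15 of 18 marked (83.3%, Fisher's exact test, adjusted p = 0.0218), 88.9% ± 15.7 (SD, n = 2), against 48.6% in CpG-matched lists, with the smoothelin gene Smtn at 18.1, Notch3 at 14.6, the smooth muscle actin gene Acta2 at 13.4 and Mylk at 11.7. Abcc9 and Rgs5, both pericyte markers, were marked in replicate 2 alone. The values of Ets1, Fli1, Egfl7, Smtn and Mylk were from peaks over 1 kb from the gene's 5′ end, near other annotated TSSs. That of Egfl7 was also at the Gm20532 promoter. The smooth muscle call ended in replicate 1 alone (adjusted p = 0.0810, exact test) and in the stronger part of the list (0.198), with a range of 0.000119 to 0.198 over 11 alternatives, and the endothelium call ended in the stronger part of the list (0.0552, range 6.02e-06 to 0.0552).

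Genes of several signalling pathways had marked promoters. All 16 Fgf signalling and feedback genes were marked, led by the feedback inhibitors Spry2 (37.5), Spred1 (35.3) and Dusp6 (31.2) and by Etv1 (21.8), a transcription factor downstream of Fgf receptors. All 16 Hippo pathway genes were marked, led by Amotl2 (33.3), the DNA-binding factors Tead3 (28.8) and Tead1 (27.1) and their coactivator Yap1 (27.5). In the Bmp and Tgfb list 21 of 24 were marked, with the inhibitory Smad7 at 43.8, the receptor genes Bmpr2 at 35.1 and Tgfbr2 at 26.8 and the Bmp target Id3 at 33.0, and with the ligand gene Bmp2 and the antagonist gene Grem1 unmarked. In the Notch list 14 of 16 were marked, with the Notch target Hes1 at 28.6, the ligand gene Jag1 at 28.2, Rbpj at 26.4 and Maml1 at 24.8, and with Hes5 and Jag2 unmarked in the replicated list, although Jag2 had weak peaks in both replicates' own lists (2.26 and 2.80). The value of Rbpj was from a peak over 1 kb from the gene's 5′ end, near another annotated TSS. Wnt signalling had 19 of 25 marked, with the feedback gene Axin2 at 45.0, Fzd1 at 33.0, Tcf7l2 at 31.6 and Fzd2 at 30.3, and with Dkk2 and Lgr5 marked in replicate 2 alone. Fisher's exact tests gave an adjusted p of 0.000178 for Fgf, 0.000178 for Hippo, 0.00140 for Bmp and Tgfb, 0.0140 for Notch and 0.0359 for Wnt. Against CpG-matched lists the Fgf and Hippo calls held (permutation test, adjusted p = 0.00768 and 0.000800), the Bmp and Tgfb and the Notch calls ended (0.439 and 0.474), and the Wnt percentage of 76.0% lay under the matched 78.9% (0.914). The Wnt call ended under 5 of 11 alternatives, replicate 1 alone among them (exact test, adjusted p = 0.0941, range 0.00623 to 0.914).

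Genes of proliferating cells and housekeeping genes were marked nearly throughout. Cell cycle genes were marked in 23 of 25 cases (Fisher's exact test, adjusted p = 0.000190). Mcm7, a replicative helicase gene whose peak also overlaps the Ap4m1 promoter, had a signal value of 25.6, the mitotic kinase gene Aurkb 23.2, Mcm6 20.5 and Birc5 19.2, while the spindle checkpoint genes Bub1 and Bub1b were unmarked in the replicated list, with weak peaks in replicate 2 alone for Bub1 (2.28) and in both replicates' own lists for Bub1b (3.55 and 3.18). All 21 housekeeping genes were marked (Fisher's exact test, adjusted p = 1.47e-05), with the actin gene Actb at 56.6, Ywhaz at 36.8, the ubiquitin gene Ubc at 33.4 and Polr2a at 32.7. The value of Ywhaz was from a peak over 1 kb from the gene's 5′ end, near another annotated TSS. Against CpG-matched lists the housekeeping call held (permutation test, adjusted p = 0.00142) and the cell cycle call ended (0.205).

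**Figure D2:**
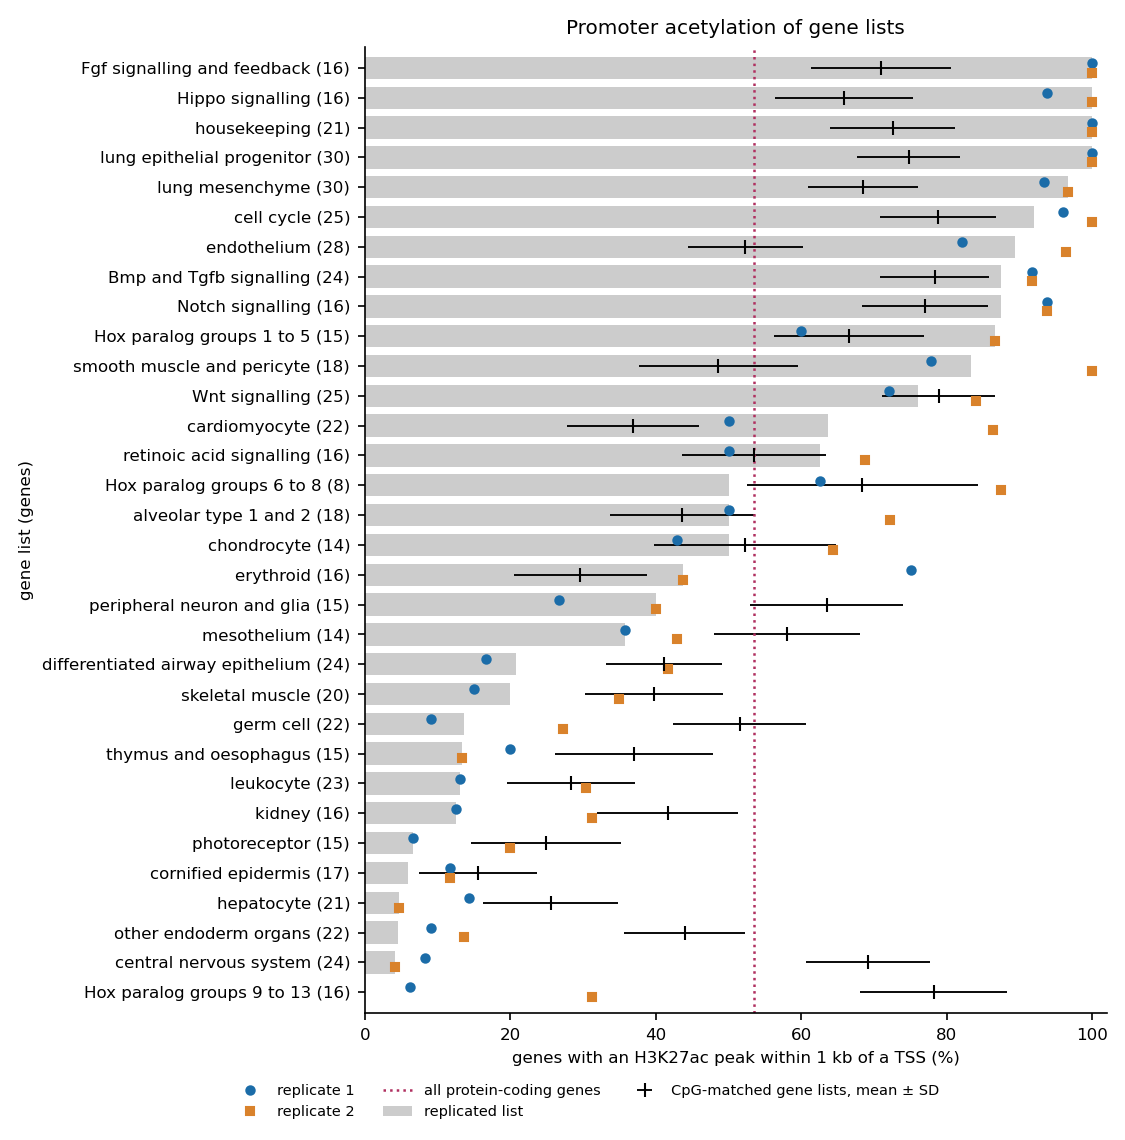
Percentage of each gene list with an H3K27ac peak within 1 kb of a TSS in the replicated list (bars), replicate 1 (circles) and replicate 2 (squares), with the mean ± SD of 10000 random lists matched on promoter CpG content (black) and the 53.5% of all protein-coding genes (dotted). Lung epithelial progenitor, Fgf, Hippo and housekeeping genes reached 100%, and Hox paralog groups 9 to 13 had 0 marked of 16 in the replicated list.

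Promoters of differentiated airway cells were mostly unmarked. In the differentiated airway epithelium list 5 of 24 were marked (20.8%, Fisher's exact test, adjusted p = 0.00281; 29.2% ± 17.7, SD, n = 2 replicates). These were Trpm5 (5.61) and Pou2f3 (5.59), markers of tuft cells, the ciliary genes Dnaic1 (5.36) and Tekt1 (2.63, chosen after its value was seen), and Foxj1 (4.88), the regulator of ciliated cells. The values of Trpm5 and Dnaic1 were from peaks over 1 kb from the gene's 5′ end, near other annotated TSSs. Of the neuroendocrine markers Ascl1 and Calca, Ascl1 was marked in replicate 2 alone and Calca in neither replicate. The call held against CpG-matched lists, at 41.1% (permutation test, adjusted p = 0.0389), and ended in replicate 2 alone, where 41.7% were marked (exact test, adjusted p = 0.125, range 0.000694 to 0.125 over 11 alternatives).

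Most leukocyte genes and most genes of organs other than lung and heart were unmarked too. Leukocyte genes were marked in 3 of 23 cases, Runx1 (10.7), a factor of blood formation, Cd68 (3.57) and Spi1 (3.57), with the macrophage genes Adgre1 and C1qa unmarked. Of 24 central nervous system genes Camk2a (5.48) was marked and the forebrain factors Dlx1 and Dlx2 were not, of 21 hepatocyte genes Proc (3.73) was marked and the fetal liver genes Afp and Ahsg were not, and of 22 genes of other endoderm organs Tshr (3.06, at the Cep128 promoter) was marked and the intestinal factors Cdx1 and Cdx2 were not. Thymus and oesophagus genes had 2 of 15 marked, Ccl25 (10.7, at the Elavl1 promoter) and Prss16 (4.03), with Aire and Cd4 unmarked. Skeletal muscle genes had 4 of 20, Tnnt3 (10.3), Mylpf (7.83, at the Tbc1d10b promoter), Actn3 (5.41, at the Zdhhc24 promoter) and Tnni2 (3.38), with Acta1 and Cacna1s unmarked. Kidney genes had 2 of 16, Hnf1b (9.59) and Cdh16 (5.38), with Aqp2 and Foxd1 unmarked. Germ cell genes had 3 of 22, Tex14 (20.2, at the Rad51c promoter), Dazl (7.49) and Spo11 (3.95), with Acrv1 and Ddx4 unmarked. Photoreceptor genes had 1 of 15, Opn1sw (5.36), and cornified epidermis genes 1 of 17, Krt10 (25.6). In the replicates' own lists, Spi1, Tnni2 and Spo11 had no promoter peak in replicate 1 and Tshr none in replicate 2. The values of Runx1, Camk2a, Prss16, Tnnt3, Cdh16 and Krt10 were from peaks over 1 kb from the gene's 5′ end, near other annotated TSSs. That of Tnnt3 was at the gene's 3′ end. Fisher's exact tests gave an adjusted p of 0.00020 for leukocyte, 3.08e-06 for nervous system, 2.14e-05 for hepatocyte, 1.47e-05 for other endoderm, 0.00466 for thymus and oesophagus, 0.00466 for skeletal muscle, 0.00281 for kidney, 0.000338 for germ cell, 0.000575 for photoreceptor and 0.00020 for cornified epidermis genes. Against CpG-matched lists the nervous system (69.1%), other endoderm (43.9%), germ cell (51.5%) and kidney (41.6%) calls held (permutation test, adjusted p = 0.000800, 0.000800, 0.000800 and 0.0101). The calls of leukocyte (permutation test, adjusted p = 0.183), hepatocyte (0.0555), thymus and oesophagus (0.0948), skeletal muscle (0.107), photoreceptor (0.186) and cornified epidermis (0.491) genes ended. Replicate 2 alone had more of these promoters marked than replicate 1 for leukocyte (30.4 and 13%), kidney (31.2 and 12.5%), germ cell (27.3 and 9.09%), photoreceptor (20 and 6.67%), other endoderm (13.6 and 9.09%) and skeletal muscle genes (35 and 15%). Over all protein-coding genes the percentages were 59.0 and 53.1%. Hepatocyte (4.76 and 14.3%), thymus and oesophagus (13.3 and 20%) and nervous system genes (4.17 and 8.33%) went the other way, and cornified epidermis genes were equal. In replicate 2 alone the kidney and skeletal muscle calls ended (exact test, adjusted p = 0.0518 for each, up to 0.0518 and 0.135 over 11 alternatives).

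A further 8 lists were not marked more or less often than other genes past the threshold, and 2 of them, of cardiomyocyte and erythroid genes, parted between the replicates. Alveolar type 1 and 2 genes were marked in 9 of 18 cases (Fisher's exact test, adjusted p = 0.842), mesothelium in 5 of 14 (0.247), peripheral neuron and glia in 6 of 15 (0.385), chondrocyte in 7 of 14 (0.842), retinoic acid signalling in 10 of 16 (0.682), and Hox paralog groups 6 to 8 in 4 of 8 (1.0). Sftpc, the surfactant gene of alveolar type 2 cells and their precursors, had a weak promoter peak (3.68). Cardiomyocyte genes were marked in 14 of 22 cases (63.6%, adjusted p = 0.470) and against CpG-matched lists, at 36.9%, they were marked more often (permutation test, adjusted p = 0.0207). The replicates gave 68.2% ± 25.7 (SD, n = 2). Of these 22 promoters 11 were marked in both replicates, 8 in replicate 2 alone and 0 in replicate 1 alone, while over all genes 1577 were marked in replicate 2 alone and 266 in replicate 1 alone. The 6 highest were Myl3 (17.2, at the Pth1r promoter), Myl4 (12, at the Cdc27 promoter), Tnni1 (7.23), Csrp3 (5.36), Gata4 (5.07) and Actc1 (4.89). The values of Tnni1, Csrp3, Gata4 and Actc1 were from peaks over 1 kb from the gene's 5′ end, near other annotated TSSs. Erythroid genes were marked in 7 of 16 cases (adjusted p = 0.528, Fisher's exact test), with 7 marked in both replicates, 5 in replicate 1 alone and 0 in replicate 2 alone.

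The 7 loci named in advance all had a peak within 1 kb of a TSS in both replicates. The Nkx2-1 gene (chromosome 12, 56531958 to 56536908, minus strand, mm10) lay under a 7.17 kb promoter peak from 56531997 to 56539164, inside a merged domain of 21.7 kb, with 4 distal peaks within 100 kb. Its strongest distal peaks ran from 56517429 to 56521939 (signal value 13.1) and from 56522167 to 56525284 (11). Both lay in introns of annotated transcripts and were part of the merged domain. Foxf1 (chromosome 8, 121084386 to 121088144) had a 7.53 kb promoter peak from 121080348 and 10 distal peaks. Tbx4 (chromosome 11, 85886422 to 85916097), a T-box factor of lung mesenchyme, had a 9.13 kb promoter peak (20.9) and 13 distal peaks. Shh (chromosome 5, 28456815 to 28467256) had a promoter peak of 9.36 kb and 5 distal peaks, the strongest from 28500047 to 28502276 in an intron (10.3). Sftpc (chromosome 14, 70520949 to 70524081) had a promoter peak of 0.351 kb and 4 distal peaks. Hoxa5 (chromosome 6, 52201754 to 52204587) lay under a peak of 8.62 kb and Hoxb5 (chromosome 11, 96303336 to 96306121) under one of 44.1 kb, the widest of the list.

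**Figure D3:**
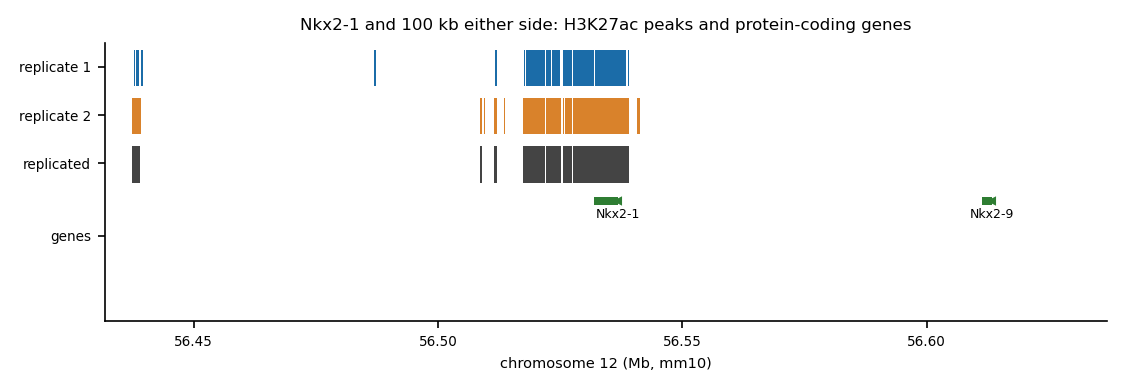
H3K27ac peaks of replicate 1, replicate 2 and the replicated list (blocks) over Nkx2-1 and 100 kb on either side, in Mb of chromosome 12 (mm10), with protein-coding genes below and triangles at their 5′ ends. Peaks sat close together in a 21.7 kb domain over Nkx2-1 and none reached Nkx2-9.

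Among the 32 gene lists, distal acetylation was densest around developmental signalling and lung identity genes. Protein-coding genes had 3.78 distal peaks on average within 100 kb, 5.26 for genes with a marked promoter and 2.06 for the others. The random lists were matched on nearby genes and not on promoter marking. Bmp and Tgfb genes had 12.1, against 4.06 in matched lists, with 32 around Smad7 and 26 around Tgfbr2. Notch genes had 11.6 (matched 3.8), lung mesenchyme 9.77 (4.06), with 29 around Ptch1 and 28 around Zeb2, and epithelial progenitor genes 9.23 (3.89, SD 1.07, with 10.8 in replicate 1 and 19.1 in replicate 2). Each of these 4 lists had an adjusted p of 0.00128 in the permutation test, from the smallest p it can give. Hippo genes had 9.88 (permutation test, adjusted p = 0.00731), with 46 around Tead1, Fgf genes 9.25 (0.0306), endothelial genes 8.86 (0.00320), with 29 around Ets1, and Wnt genes 8.56 (0.0160). Hox paralog groups 9 to 13 had 0 (matched 3.10, permutation test, adjusted p = 0.00128), and the other 23 lists did not pass, of which cornified epidermis (0.0663) did so under 4 of 9 alternatives, with fewer peaks (range 0.0128 to 0.331). The Fgf call ended with either replicate alone (permutation test, adjusted p = 0.0646 and 0.0672, range 0.00320 to 0.125 over 9 alternatives), the Wnt call in replicate 1 alone (0.0512, range 0.00183 to 0.147) and that of Hox groups 9 to 13 with a 200 kb window (0.176, range 0.00107 to 0.176). Counts cover a longer stretch for genes with TSSs far apart, and around the 5′ end alone Tead1 had 24 distal peaks, Ets1 24, Zeb2 21 and Fgfr2, with TSSs 2955 kb apart, 18 instead of 43, while all 9 calls held.

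The Hoxa and Hoxb clusters were acetylated over their anterior genes, and the Hoxc and Hoxd clusters were almost bare. Hox genes set position along the body axis, and paralog groups of low number are the anterior ones. Peaks of the replicated list covered 48.0% of the Hoxa cluster (41.8% in replicate 1 and 51.9% in replicate 2) and 34.6% of Hoxb (33.3% and 36.2%). They covered 0.809% of Hoxc and 0.459% of Hoxd, where replicate 1 had 0 peaks and replicate 2 had 11 and 4. In paralog groups 1 to 5, 13 of 15 promoters were marked (adjusted p = 0.0140, Fisher's exact test), with Hoxb3, Hoxb4 and Hoxb5 under a shared peak (37.5) and Hoxa4 at 26.1, and Hoxb1 and Hoxd1 unmarked. Of the 15, 9 were marked in both replicates and 4 in replicate 2 alone. Hoxc4, Hoxc5, Hoxd3 and Hoxd4 counted as marked, though the replicated peaks of their clusters were weak (2.98, 3.20 and 3.95). In groups 9 to 13, 0 of 16 were marked (adjusted p = 2.14e-05), with Hoxa10 and Hoxa11 marked in replicate 2 alone, against 78.2% in CpG-matched lists (permutation test, adjusted p = 0.000800). The call of groups 1 to 5 ended against CpG-matched lists (0.134) and in either replicate alone (Fisher's exact test, adjusted p = 0.0518 and 0.705, range 0.0126 to 0.705 over 11 alternatives). That of groups 9 to 13 ended in replicate 2 alone (0.0518, range 7.47e-06 to 0.0518), where 31.2% were marked, against 6.25% in replicate 1.

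**Figure D4:**
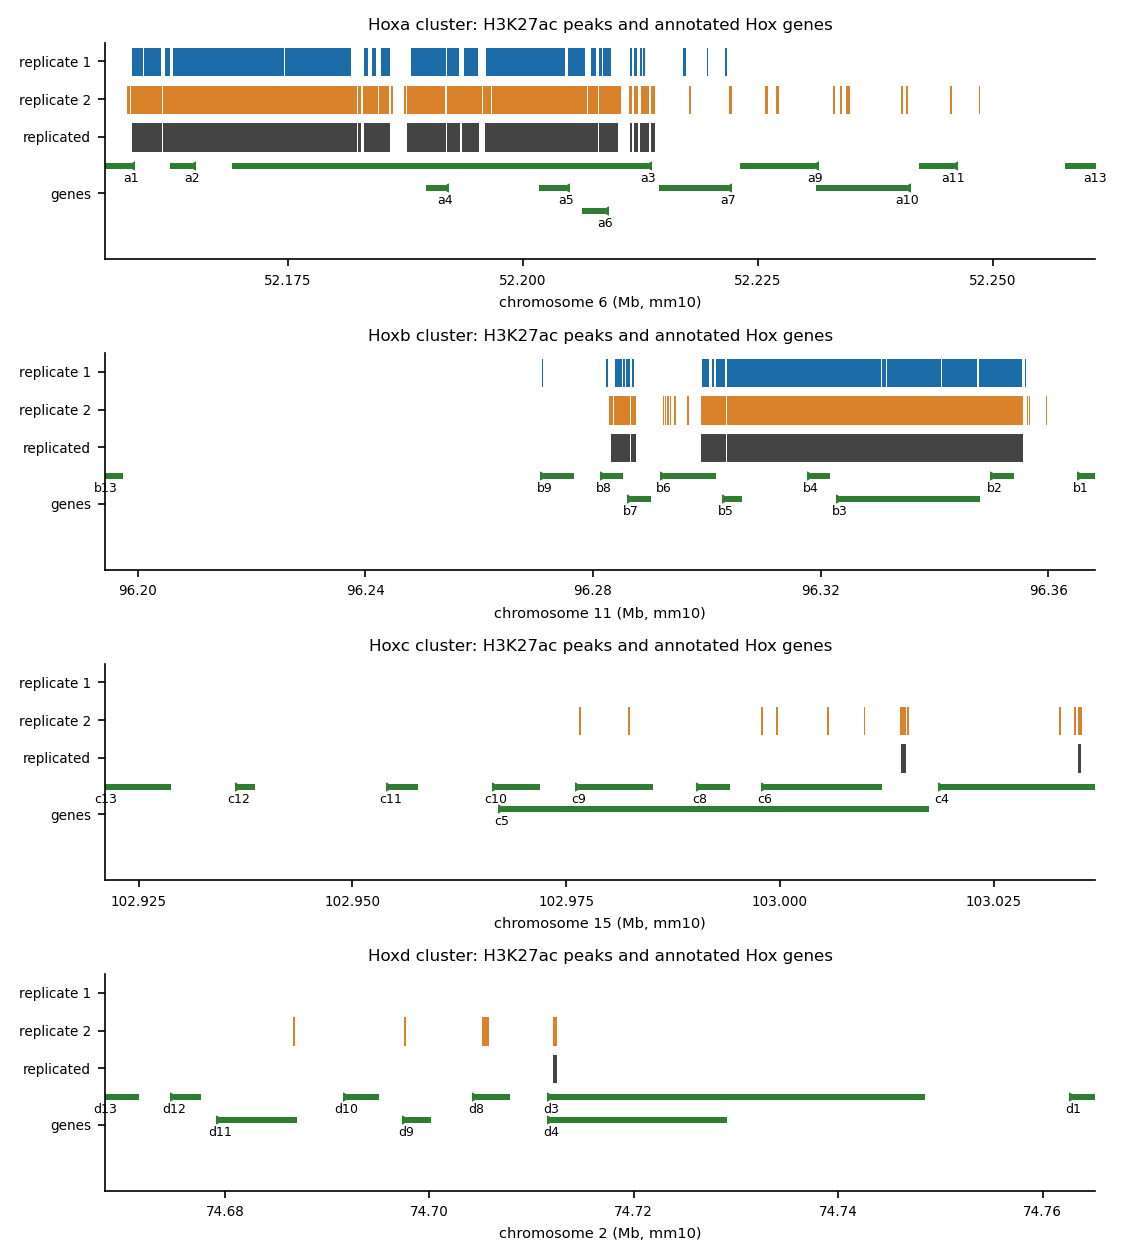
H3K27ac peaks of each replicate and of the replicated list (blocks) along the Hoxa, Hoxb, Hoxc and Hoxd clusters, in Mb (mm10), with Hox genes drawn from annotated start to end and triangles at their 5′ ends. Replicated peaks covered 48.0% of Hoxa and 34.6% of Hoxb, at the anterior genes, and under 1% of Hoxc and Hoxd.

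Genes of the epithelial progenitor and mesenchyme lists had broad domains of acetylation more often than other genes. Domains over a TSS had a median width of 1.55 kb among 10327 genes, and the 500 genes with the widest had at least 5.20 kb. The widest, 56.5 kb, ran over Hoxb2 to Hoxb6 (chromosome 11, 96298928 to 96355469), and the domain at Hoxb3 to Hoxb5 was 56.9 kb wide in replicate 1 and 57.9 kb in replicate 2. Next came Smad7 (30.3 kb), Nr2f2 (29.6 kb), a nuclear receptor, Hoxa2 and Hoxa3 (27.5 kb), Actn4 (25.5 kb), Vgll4 (22.8 kb), Hoxa4 to Hoxa6 (22.5 kb), a histone gene cluster with Hist1h1a (22.3 kb), Egfl7 (21.8 kb) and Nkx2-1 (21.7 kb). The replicates differed in the domains of Actn4 (5.92 and 27.1 kb), Egfl7 (8.76 and 23.0 kb) and Smad7 (15 and 33.2 kb). The domain at Hoxa3 was 2.75 and 28.2 kb wide, but in replicate 1 a gap of over 1 kb cut it off. Beyond that gap, replicate 1 peaks from 52158476 to 52181669 merged into a domain over Hoxa2. Of epithelial progenitor genes with a domain, 12 of 29 were among the 500 widest (41.4%, against 4.74% of other genes, Fisher's exact test, adjusted p = 5.16e-08), and of mesenchyme genes 11 of 28 (39.3%, adjusted p = 3.01e-07), with Ptch1 at 21.4 kb (13.3 and 27 kb in the replicates) and Zeb2 at 19.7 kb. All 8 Hox genes of groups 1 to 5 with a domain were among them (adjusted p = 8.30e-10, exact test), but neighbours share merged domains and this list was also called in simulated data where it was not planted. Retinoic acid (3 of 8, 0.0305), Hippo (4 of 15, 0.0305) and Hox groups 6 to 8 (2 of 3, 0.0328) also passed the exact test and did not pass under 4, 4 and 2 of 9 alternatives (highest adjusted p = 0.240, 0.436 and 0.416). Bmp and Tgfb genes, not called here (exact test, adjusted p = 0.0576), passed under 8 of 9 alternatives (range 0.000525 to 0.0593), housekeeping genes (0.0576) under 4 (0.0166 to 0.778) and smooth muscle genes (0.0651) under 1 (0.0232 to 1.0).

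Stitched distal clusters lay near a varied set of genes. The 16240 clusters included 7836 with at least 2 peaks. The highest (chromosome 1, 86433498 to 86509918, 20 peaks over 76.4 kb) was nearest to Tex44, and it ranked 2 in each replicate's own list. The other 9 were nearest to Cstad (2 clusters), Zfp36l1 (2 clusters), Bcas3, Ncor2, Ski, a repressor of Tgfb signalling, Creb3l2 and Btg2. The clusters nearest to Zfp36l1, an RNA-binding protein gene, lay 89.2 and 191 kb from its TSS, so the nearest gene need not be their target. Of epithelial progenitor genes nearest to a cluster, 7 of 26 were nearest to 1 of the top 500 (26.9%, against 6.12% of other genes, Fisher's exact test, adjusted p = 0.0235). This was the only list that passed, and it did not pass in the pooled list (exact test, adjusted p = 0.189), in the stronger part of the replicated list (0.291), with −log10 q of at least 5 (0.0763) or ranked by summed width (0.0602, range 0.00244 to 0.291 over 7 alternatives). Mesenchyme (exact test, adjusted p = 0.199) and Bmp and Tgfb genes (0.212) each passed under 2 of 7 alternatives (lowest 0.0145 and 0.0141).

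The TEAD, E-box, FOX and NKX2 sequences were more common at distal summits than in GC-matched windows and the NFY sequence was rarer. The FOX and NKX2 results did not hold against flanking windows, and calls of 5 further sequences depended on the processing. The TEAD consensus was in 4.15% of 35201 windows, 1.29 times the background (Fisher's exact test, adjusted p = 4.91e-10), and the E-box CAGCTG in 15.2% (1.30 times, 2.28e-42). The FOX consensus was in 23.5% (1.17 times, 3.76e-26), the NKX2 consensus, bound by Nkx2-1 and its relatives, in 7.90% (1.18 times, 4.64e-09), GATA in 2.38% (1.16 times, 0.00988) and AP-1 in 3.77% (1.1 times, 0.0331). The replicates' own ratios were 1.32 ± 0.0956 for TEAD, 1.15 ± 0.0379 for FOX and 1.21 ± 0.0273 for NKX2 (mean ± SD, n = 2). The NFY consensus, a promoter element, was rarer than in the background (5.47% against 10.2%, 0.539 times, 1.18e-118), and so were CTCF (0.597 times, 0.0331), SOX (0.830 times, 0.0390) and TBX (0.843 times, 0.0481). The other 12 motifs did not pass, though MEF2 (adjusted p = 0.0930, exact test) did under 6 of 8 alternatives (range 1.92e-09 to 0.488). Windows were matched on GC content alone. Without repeat-masked bases 16122 windows remained, and there SOX was more common at summits (1.42 times, Fisher's exact test, adjusted p = 0.0186), MEF2 passed (1.71 times, 0.0436), and GATA (0.482), AP-1 (0.531) and TBX (0.482) did not. Against flanking windows 3 kb away, which are not matched on GC content, FOX was rarer at summits by 6.87 percentage points and NKX2 did not pass (exact test, adjusted p = 0.475, range 9.68e-31 to 0.475 over 8 alternatives). The TBX call ended under all 8 alternatives, the CTCF call under 6, the GATA call under 5 (exact test, adjusted p 3.18e-06 to 0.842) and the AP-1 call under 4 (6.92e-12 to 0.658).

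**Figure D5:**
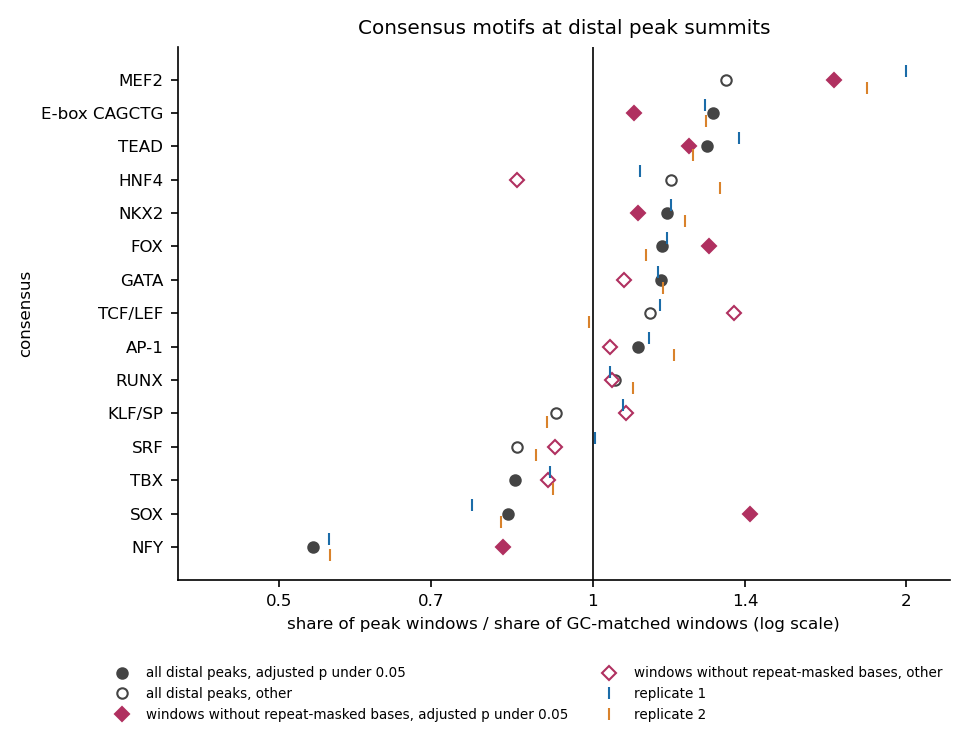
Ratio of the share of distal peak windows with a consensus to that of GC-matched windows (log scale) for consensus sequences present in at least 100 peak windows and 50 background windows, for all distal peaks (circles), windows without repeat-masked bases (diamonds) and each replicate (ticks), filled where the adjusted p was under 0.05. FOX, TEAD, NKX2 and the E-box lay above 1 in both sets of windows and NFY below 1, while SOX lay on both sides.

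Peaks found in 1 replicate were weaker, narrower and less often at promoters than shared peaks. Replicate 1 had 15326 such peaks (21.5% of its list), of which 84.2% lay in the weaker part of the list, with a median width of 217 bp against 372 bp for shared peaks. Replicate 2 had 73774 (60.3%), of which 68.2% lay in the weaker part, with a median width of 238 bp against 610 bp. Promoters held 14.8% of the peaks found in replicate 1 alone, against 34.3% of its shared peaks, and 13.8% against 34.9% in replicate 2. Introns held 49.8% and 52.7% of them. With 1 sample on each side, these peaks were not tested between the samples.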

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

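Chosen only after the result was seen were the tests of shortened replicate 2 against replicate 1 on the fixed and second cardiac lists and on the fixed and second hepatocyte lists. The design has 1 group and names no biological difference, so none was tested for any pattern, and the cell types below were tested only as sources of signal. In data outside the comparisons, 9 peaks of the replicated list lay on sequences that are not part of chromosomes 1 to 19, X or Y. Of these 4 were on unplaced sequences, 3 on sequences assigned to chromosome 4 and 2 on sequences assigned to X, with a highest signal value of 38.3. Replicate 1 had 9 such peaks and replicate 2 had 10.

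Cardiomyocyte promoters were marked in 63.6% of cases, against 36.9% in CpG-matched lists, 11 of 22 in both replicates, 8 in replicate 2 alone and 0 in replicate 1 alone. The longer list of replicate 2 did not account for all of the difference between replicates. A second list of 25 cardiac genes, which shares no gene with any other list, was written because of this pattern, before its values were seen. It was marked at 36% in replicate 1 and 80% in replicate 2, or 60% with equal numbers of peaks. That left 24 points (CpG-matched lists 1.42, SD 5.41, permutation p = 0.0006 over genes, with 1 sample on each side). More heart muscle cells in replicate 2 would require such a difference. The fixed list, picked because it parted, differed by 22.73 points. The second hepatocyte list also shifted to replicate 2, by 17.4 points (CpG-matched lists 1.12, SD 5.21), and the fixed hepatocyte list the other way (−14.3 points). The shift is thus not particular to heart genes and cannot single out heart muscle cells. In the replicated list 44% of the second cardiac list were marked. This lay under the bound set beforehand against heart muscle cells in the samples (56.2%, the CpG-matched mean plus 1 SD, permutation p = 0.839). The bound does not exclude them, because 9 fixed lists of organs other than lung and heart lay under their matched means, at 20% or less. The second hepatocyte list, at 21.7%, lay near its own matched mean (24.6%), however. This comparison with other organs was not part of the prediction set beforehand. Whether heart muscle cells were in both samples therefore cannot be told apart from their absence; among the most strongly marked cardiac genes were Myl3 (17.2, at the Pth1r promoter), Myl4 (12, at the Cdc27 promoter), Tnni1 (7.23) and, in the second list, Myom1 (47.2), while Myh6 (3.57) and Myl7 (2.87) were weak and Nppa was unmarked. The muscle of pulmonary veins, heart tissue carried along in dissection and differences between the embryo pools stay open as sources, untested, and expression of these genes in lung was not measured here.

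Erythroid promoters were marked in 75% of cases in replicate 1 and 43.8% in replicate 2, although replicate 2 has the longer list. A second list of 24 erythroid genes that shares no gene with any other list went the same way, at −29.17 points for replicate 2 with equal numbers of peaks (CpG-matched lists 1.47, SD 5.16, permutation p = 0.0002, the smallest it can give), so more red blood cell precursors in replicate 1 are a candidate source. Liver tissue carried along in replicate 1 was tested with a second list of 23 hepatocyte genes, of which 13.04% were marked in replicate 1. This lay under the bound set beforehand (32.4%, the CpG-matched mean plus 1 SD, permutation p = 0.223). Like the fixed hepatocyte list at 14.3%, it lay within the 6.67 to 20% of 8 lists of other organs there, with Alb and Afp unmarked. Here too the comparison with other organs was not part of the prediction. These values argue against a hepatocyte signal above that of other organs. The hepatocyte lists cover no other cells of the liver. The erythroid lists cannot show which tissue red blood cell precursors came from, so liver tissue is not excluded as their source. With equal numbers of peaks the fixed hepatocyte list was marked more in replicate 1 (−14.3 points for replicate 2, permutation p = 0.0268). The second hepatocyte list was marked less there (17.4 points, permutation p = 0.0104). In replicate 1 alone the globin genes Hbb-bs (4.52) and Hba-a2 (3.38), Spta1 (4.39) and Alas2 (3.72) had weak promoter peaks, and Tfrc (13.9) and Klf1 (9.17) had stronger ones in the replicated list, all chosen after their values were seen. Blood left in the tissue, the vessels of the lung and differences between the embryo pools remain open and untested.

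The NFY consensus was rarer at distal summits than in GC-matched windows, at 0.539 times. Without repeat-masked bases on either side the ratio was 0.8195, between the bounds set beforehand for repeats as the cause (0.9 or more) and against it (under 0.75). The reversed consensus, which has the same bases, had a ratio of 0.7721, also between its bounds, and 0.954 without repeat-masked bases. Repeats and base composition other than GC may thus each carry part of the difference, and their shares cannot be told apart with these windows.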

How the results depend on the processing

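Chosen only after the main result was seen were the alternatives for the 32 lists with replicate 2 shortened to the length of replicate 1's list, with distal peaks around the 5′ end alone and with a background free of olfactory and vomeronasal receptor genes, and that for the 22 motifs with windows free of repeat-masked bases. Of the 24 gene lists called at promoters, 8 kept their direction and side of the threshold under all 11 alternatives: epithelial progenitor, mesenchyme, housekeeping, Fgf, Hippo, other endoderm organs, nervous system and germ cell, with the highest adjusted p at 0.00768. For distal counts 6 of 9 lists did so under all 9 alternatives (epithelial progenitor, mesenchyme, endothelium, Bmp and Tgfb, Notch, Hippo, highest adjusted p 0.0247), for domains 3 of 6 under all 9 (epithelial progenitor, mesenchyme, Hox groups 1 to 5, highest 0.000521), where Bmp and Tgfb genes gained a call under 8 of 9, and for motifs TEAD, the E-box and NFY under all 8 (highest 0.00220). The cluster call of epithelial progenitor genes passed under 3 of 7. Over all single lists, genes, domains, clusters and motifs, 1559 values stayed as reported, 73 lost and 43 gained a call with the same direction, 39 turned, and some values without a test moved. Over the totals, 82 stayed and 46 moved. The causes were not tested, except where the setting itself holds fewer peaks or a wider window.

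Overlap between replicates fell to 38.6% of replicate 1 and 22.5% of replicate 2 when at least 50% of each peak had to overlap, which put 61.4% and 77.5% of peaks in 1 replicate only and gave a rho of 0.796. It was 70.2% and 25.1% with 50% of the counted peak, 69.5% and 57% with equal numbers of peaks, and 92.7% and 46.6% at −log10 q of at least 5 in both lists. Promoter, exon, intron and intergenic percentages were 43.8, 2.94, 31.9 and 21.4% in the stronger part of the replicated list and 38.3, 3.22, 35.6 and 22.9% at −log10 q of at least 5. With a 2.5 kb promoter window they were 39.5, 2.52, 35.0 and 23.0%, as a wider window takes peaks from the other classes, and with 500 bp exons held 4.54% and intergenic sequence 26.2%. With a replicate left out they ranged from 22.2 to 30.1%, 3.98 to 4.41%, 41.2 to 46.9% and 24.7 to 26.5%.

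Differences from other genes in promoter marking, in percentage points, turned direction for 7 lists, only Wnt of which had been called. Against CpG-matched lists 6 lists were lower, and the differences turned for Wnt (−2.86), alveolar (6.38) and erythroid (14.1) genes. They turned in the pooled list for Hox groups 6 to 8 (30.9) and chondrocyte (7.72), with a 2.5 kb window for alveolar (6.03) and chondrocyte (9.21), with 500 bp for cardiomyocyte (−2.77), and with the 5′ end alone for retinoic acid (−12.1). They turned in the stronger part of the list for cardiomyocyte (−15.5) and Hox groups 6 to 8 (2.70), at −log10 q of at least 5 for cardiomyocyte (−4.51) and Hox groups 6 to 8 (0.0388), and in shortened replicate 2 for Hox groups 6 to 8 (20.6) and chondrocyte (2.71). With a replicate left out the ranges were −3.05 to 13.2 for alveolar, −15.3 to 22.0 for erythroid, −10.2 to 5.25 for chondrocyte, −3.05 to 9.72 for retinoic acid, 9.45 to 28.5 for Hox groups 6 to 8 and −3.05 to 27.4 for cardiomyocyte genes. The cardiomyocyte list passed in replicate 2 alone (Fisher's exact test, adjusted p = 0.0151, range 0.0151 to 0.889 over its alternatives).

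Lists with fewer distal peaks numbered 2 in the pooled list, 3 with a 50 kb window, 0 with 200 kb and 2 to 2 with a replicate left out, and the erythroid difference became −0.343 peaks per gene in the stronger part of the list. The domain difference of smooth muscle genes became −5.17 points at −log10 q of at least 5. The number of lists near top clusters was 0 in the pooled list, 0 in the stronger part, 0 at −log10 q of at least 5, and 2 to 3 with a replicate left out.

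The number of motifs that were more common was 3 against flanking windows and 9 to 10 with a replicate left out, and of rarer motifs 1 in the stronger part, 2 at −log10 q of at least 5, 2 without repeat-masked bases and 2 to 4 with a replicate left out. Against flanking windows, differences in percentage points turned for FOX (−6.87), GATA (−0.147), KLF/SP (0.187), MEF2 (−0.0628), RUNX (−0.767) and SOX (0.00802). They turned with 50 bp on either side for RUNX (−0.0457) and TBX (0.00846), in the stronger part for HNF4 (−0.0283) and KLF/SP (0.00688), and without repeat-masked bases for HNF4 (−0.0622), KLF/SP (0.0309) and SOX (0.291). With a replicate left out the range was −0.0649 to 0.0452 for KLF/SP and −0.115 to 0.00470 for SRF. The lists hold no read counts, so what depth limits could not be measured.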

Other observations

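The gene families and single genes in this part were chosen after their values were seen, and no test was made on them. Families of genes for basic cell functions were marked nearly throughout. Ribosomal protein genes were marked in 79 of 82 cases (96.3% in each replicate) and histone genes in 61 of 67. NADH dehydrogenase subunit genes were marked in 41 of 46 cases and proteasome subunit genes in 35 of 40. Receptor families of sensory neurons were almost bare, with 2 of 1134 olfactory receptor genes and 1 of 328 vomeronasal receptor genes marked, and so were the defensins (0 of 64), the clustered protocadherins (3 of 56) and the Sprr and Lce genes of the epidermal barrier (0 of 36). Collagen genes, which build the matrix, were marked in 26 of 44 cases and had 9.91 distal peaks per gene, and integrin genes, whose products bind that matrix, had 9.50, against 3.78 over all protein-coding genes. Semaphorin guidance genes were marked in 15 of 20 cases (80% in replicate 1 and 95% in replicate 2). Wnt ligand genes were marked in 5 of 19 cases.

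Among genes that code for no protein, Dnm3os (36.1), a transcript of mesenchyme that carries microRNAs, the nuclear transcripts Malat1 (31.6) and Neat1 (23.2), Carmn (29.3), a smooth muscle transcript, and the imprinted H19 (22.2) had strongly marked promoters. The highest signal value of the replicated list, 65.5, was at a 2.43 kb peak on chromosome 5 (115488702 to 115491133) over the small nuclear RNA genes Gm24265 and Gm24407, followed by the promoters of Tnrc18 (62.0) and, 3.30 kb from the nearest coding TSS, Setd1b (60.9). On the X chromosome 34.8% of promoters were marked, with 5.60 peaks per Mb, and chromosome 11 had 38.1 per Mb. Of alveolar genes, Lpcat1 (22.2), a phospholipid enzyme of surfactant synthesis, and Cldn18 (13.7), a tight junction gene, had the highest promoter values, and the surfactant genes Sftpa1 and Sftpd were unmarked in the replicated list. Among epithelial progenitor genes, the forkhead factors Foxa2 (19.4) and Foxa1 (18.6) had higher values than Sox9 (8.71), a marker of the tips of branching tubes, and Sox2 (9.17), a marker of the stalks.

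Of the 59767 replicated peaks, 14970 did not overlap a peak of each replicate by even 1 bp. At 50% of either peak the number was 15407. Why these peaks are in the list was not tested.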
